A study of Mus musculus with 2 samples.

How the data were processed

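Single-nucleus RNA was measured in quadriceps muscle of male C57BL/6J mice, 1 library from a mouse after sham surgery (control) and 1 from a mouse after injection of KPCY tumour cells into the pancreas (KPCY). Per the labels' protocols, nuclei were released from minced muscle, sorted as DAPI-positive, captured with the 10x Chromium 3' v3 kit and sequenced on a NextSeq 2000. Per the submitters' processing notes, Cell Ranger 6.0.1 and Seurat (no version given) were used with the builds mm10 and GRCm38.p5. The deposited matrices hold raw counts (UMIs per gene and nucleus) and, per their file names, are already filtered to called barcodes. Whether intronic reads were counted is not given in the sources used here. Groups were taken from the labels, and with 1 library per group neither a batch nor the sampling time can be told from the group.

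The control and KPCY libraries held 36849064 and 27446235 UMIs in 10733 and 10870 barcodes, with at least 501 and 500 UMIs in each, and 20784 and 19434 detected genes. The 3 features added to the reference by the authors (a GFP, tdTomato and CreERT2) had 0 UMIs in both libraries. Nuclei with fewer than 200 genes (1 control, 0 KPCY) or over 5% of UMIs from mitochondrial genes (46 control, 131 KPCY) were left out. Scrublet (in scanpy 1.11.5, expected doublet rate 0.08) called 0 control and 2 KPCY nuclei, so the doublet caller did not work here and doublets remain. An alternative that removes the 8% of nuclei with the highest scores was therefore added.

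Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes and 30 principal components gave a graph of 15 shared nearest neighbours. Both libraries were clustered together without integration by the Leiden method (igraph 0.11.9, resolution 0.8), which gave 23 clusters. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, figures matplotlib 3.10.9, and TMM factors edgeR 4.0.16 in R 4.3.3. Clusters were named from 24 marker sets by mean log2 enrichment over the library (10 CPM added before logs). A cluster was myonuclear when no other type reached 1 and the level of 4 core myofibre genes (Ttn, Neb, Ryr1 and Dmd) was at least 0.5 of the library level. Another name needed an enrichment of at least 2, a core level under 0.5 and a next type under 0.6 of the first. The markers were fixed before the files were seen, but these limits were set after the clusters had been seen. Names carry "-like" because they rest on transcripts alone.

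Raw counts were summed over the nuclei of a class in each library and scaled to CPM. Intervals are 95% limits (exact Poisson for CPM, exact binomial for shares, exact conditional for ratios), cover counting error only, and leave out differences between mice. A count of 0 was set to a floor of 3 counts over the class sum and is printed as a bound. Genes were ranked when they had at least 100 UMIs over both sums, and list members counted as measured from 30 UMIs. The 38 gene lists, in 56 pairs of list and class, were summarised by the median log2 ratio, the number of members at least 1.5-fold apart, and the percentile among 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries. Myonuclear FoxO, sarcomere and stress lists share members with other lists.

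Named genes followed a rule fixed beforehand: the 10 highest and 10 lowest log2 ratios among ranked genes in myonuclei and FAP-like nuclei, 5 and 5 in endothelial-like and macrophage-like nuclei, 3 and 3 in any other class with enough nuclei (mural-like), and up to 2 highest and 2 lowest measured members of each list. Pdgfra, Dcn, Col1a1, Col3a1, Fbxo32, Trim63, Mstn, Foxo1, Fkbp5, Pdk4, Myh4, Myh1, Myh2, Pax7, Vwf and Mrc1 were always taken. Unnamed gene models, mitochondrial and ribosomal protein genes were passed over, and some genes that the rule took are not reported here. Coordinates come from GENCODE vM21, in which 27722 of 28001 features were found. Cebpd was the only list member absent from the files. The counts of near-identical copies (Acot1 and Acot2, C4b, H2-K1, Mt2) and of overlapping genes are uncertain.

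The lists, markers, named-genes rule, thresholds and 16 alternatives were chosen before the data were examined. These alternatives were 500 genes per nucleus, no mitochondrial limit, no doublet removal, Leiden resolutions of 0.4 and 1.6, each library clustered on its own, TMM scaling, the mean of single nuclei, thinning to 500 UMIs per nucleus, subtraction of free RNA, ranking from 30 or 300 UMIs, list members from 100 UMIs, type IIb-like clusters alone (at least 80% Myh4 among myosin UMIs, which in KPCY rests on few Myh4 UMIs), nuclei with at least 1000 UMIs, and shares outside the myonuclear clusters. Free RNA was estimated from contractile genes in classes outside myonuclei and subtracted with the whole-library profile, and RNA from doublets counts toward the same estimate. Added after the data were seen were removal of the 8% highest doublet scores, shares without the unnamed clusters, the median of all genes set to 0, nuclei with under 1% of UMIs from core myofibre genes, and clustering without genes at least 2-fold apart between the libraries. The procedure was tested on simulated data with 100 genes set 4-fold and 100 set 8-fold apart: in sums of myonuclear and FAP-like size 100% were found at least 2-fold apart, against 0.00817% and 0.511% of unchanged genes, and intervals of unchanged genes covered the true value in 95.7% and 96.2%. Both simulated sums came from the control profile with counting noise alone. The test therefore checks the calculation and says nothing on differences between mice, library preparation or muscle fibre RNA.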

Results

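Nuclei of mouse quadriceps muscle were profiled by droplet RNA sequencing (10x Genomics 3' chemistry), in which each transcript is counted once by its unique molecular identifier (UMI). The control library came from muscle after sham surgery and the KPCY library from muscle after injection of KPCY cells, a mouse pancreatic tumour line, into the pancreas, a model of the muscle wasting of cancer (cachexia). Each group held 1 library, so no difference below has a replicate check, no test was possible, and what separates the tumour from the library cannot be known. The control library held 10733 barcodes and 36849064 UMIs, with a median of 3018 UMIs and 1379 genes per nucleus. The KPCY library held 10870 barcodes and 27446235 UMIs, with a median of 1994 UMIs and 1045 genes. After filtering, 10687 control and 10737 KPCY nuclei remained. Expression is given as CPM, the UMIs of a gene in the nuclei of a class scaled to the same total in each library, control first, and brackets hold 95% intervals that cover counting error only. Intervals are printed for leading values and for most values that rest on fewer than 30 UMIs of a gene.

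The first comparison asked which cell types made up the muscle of each library. Myonuclei, the nuclei of the muscle fibres, formed 66.1% [65.2 to 67.0] of control nuclei (7067) and 81.4% [80.6 to 82.1] of KPCY nuclei (8738). Nuclei like fibroadipogenic progenitors (FAPs), the Pdgfra-expressing stromal cells that make muscle matrix and fat, formed 16.6% [15.9 to 17.3] of control nuclei (1777) and 5.45% [5.03 to 5.89] of KPCY nuclei (585), a ratio of 0.328. Macrophage-like nuclei were at 2.16% [1.89 to 2.46] and 0.550% [0.419 to 0.708], a ratio of 0.254. Endothelial-like nuclei were at 3.18% [2.86 to 3.53] and 3.36% [3.03 to 3.72], but their order depends on the processing, with a log2 ratio of 0.08 here, 0.96 with no mitochondrial limit, -0.79 from 500 genes per nucleus and -1.83 with each library clustered on its own.

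Of all kept nuclei, tenocyte-like nuclei formed 0.702% [0.552 to 0.879] in control and 0.251% [0.166 to 0.366] in KPCY, muscle stem cell-like nuclei 0.627% [0.486 to 0.796] and 0.205% [0.128 to 0.310], and perineurial-like nuclei, from the sheath of nerves, 0.533% [0.404 to 0.690] and 0.214% [0.136 to 0.321], but outside the myonuclear clusters the intervals of all 3 overlapped between the libraries. Mural-like nuclei, from pericytes and smooth muscle, were at 1.39% and 0.959%, an order that turned round at a coarser clustering (log2 ratio 0.08) and outside the myonuclear clusters (4.12% and 5.15%). Among nuclei outside the myonuclear clusters the FAP-like share was 49.1% [47.4 to 50.7] in control and 29.3% [27.3 to 31.3] in KPCY, and the endothelial-like share 9.39% and 18.1%. The macrophage-like share there was 6.38% [5.61 to 7.23] and 2.95% [2.25 to 3.79], a ratio of 0.463.

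FAP-like nuclei came from cluster 5 in the control library and cluster 12 in the KPCY library, so the class was also counted after clustering without the 8154 genes that lay at least 2-fold apart between the libraries in a class, a choice made after the data were seen. A single cluster shared by both libraries then held 16.1% [15.4 to 16.8] of control and 5.53% [5.11 to 5.98] of KPCY nuclei as FAP-like, and myonuclei were at 66.6% and 82.9%. Clusters that met no naming rule held 8.65% of control and 7.63% of KPCY nuclei. The main unnamed KPCY cluster (804 nuclei, more than the 585 FAP-like) mixed endothelial, FAP and muscle fibre transcripts. Its median doublet score was 0.221, against 0.107 in the KPCY library, so doublets are not excluded there. The same holds for the main unnamed control clusters, with scores of 0.278 each against 0.0957 in the control library. Cluster 9 (726 control nuclei) mixed haemoglobin, FAP and muscle fibre transcripts. Cluster 17 (151 control nuclei) mixed endothelial, macrophage and muscle fibre transcripts. Nuclei were shallower in KPCY, with median UMIs of 1716 and 926 in FAP-like nuclei and 3429 and 2076 in myonuclei, except for endothelial-like nuclei (1205 and 1423). Endothelial-like nuclei carried much muscle fibre RNA in the KPCY library: 39.6% of them had at least 1% of their UMIs from core myofibre genes, against 0.294% in control, and without those nuclei the endothelial-like shares were 3.17% and 2.03% [1.77 to 2.32].

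**Figure D1:**
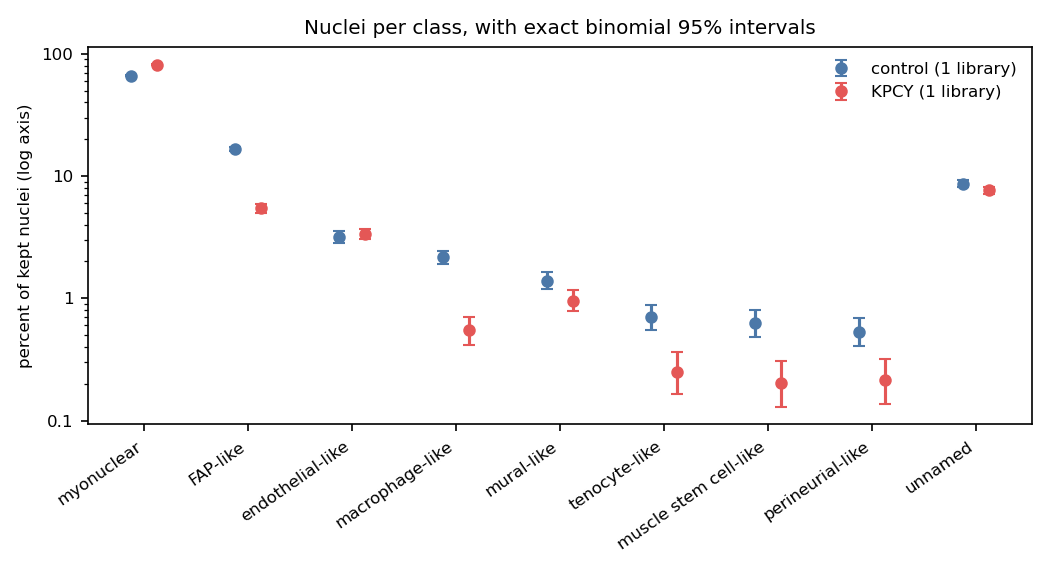
Percent of kept nuclei in each class (log axis) for the control and KPCY libraries, 1 point per library with exact binomial 95% intervals. FAP-like nuclei lie at 16.6% and 5.45%, macrophage-like nuclei at 2.16% and 0.550%, and endothelial-like nuclei at 3.18% and 3.36%, an order that depends on the processing.

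The second comparison asked how transcription in muscle fibres differed. In myonuclei of the KPCY library the atrophy genes Fbxo32 and Trim63 stood far above control, and proteasome subunits were higher as a group. Most genes of the fast contractile apparatus stood well below control. Fbxo32 (atrogin-1), an E3 ubiquitin ligase of muscle atrophy, was at 191 [186 to 197] CPM in control and 7540 [7504 to 7576] in KPCY, 39.4-fold higher. Trim63 (MuRF1), a ligase that marks sarcomere proteins for degradation, was at 301 [295 to 308] and 10279 [10237 to 10321], 34.1-fold higher. Myh4, the fast myosin of type IIb fibres, was at 4940 [4913 to 4967] and 263 [256 to 270], 18.8-fold lower. Fbxo32 lies on chromosome 15 (58175879 to 58214932), Trim63 on chromosome 4 (134315120 to 134329629) and Myh4 on chromosome 11 (67238029 to 67260446) of the mm10 assembly.

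Of the 18 ubiquitin ligases of muscle atrophy, 12 were at least 1.5-fold higher and 3 at least 1.5-fold lower in KPCY myonuclei. The median log2 ratio was 0.91, at percentile 98.6 of 10000 expression-matched random lists. Stub1 (37.5 and 13.5 CPM) and Trim32 (2.22 and 0.985, log2 -1.17 [-1.95 to -0.44]) lay lower. All 32 proteasome subunits had ratios above 1, and 31 of them were at least 1.5-fold higher, with a median of 2.11 (percentile 100). Psmd13 was at 25.4 and 208 CPM and Psmc4 at 10.2 and 68.3, whereas Psmd7 differed least (95.1 and 130, log2 0.45). In the autophagy and lysosome list 21 of 33 members were higher and 1 lower (median 0.92). Gabarapl1, a component of autophagosome membranes, was at 9.38 and 108 CPM, and Bnip3, a receptor of mitophagy, at 75.2 and 822. Vps13c was the lower member, at 122 and 40.2.

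The widest median among the lists was that of the FoxO and glucocorticoid response, at 2.79 (percentile 100), with 20 of 25 members higher and 2 lower. Foxo1, the transcription factor upstream of the atrophy ligases, was at 93.1 and 1431 CPM. Fkbp5, a classic glucocorticoid receptor target, was at 67.8 and 1011, Ddit4, an inhibitor of mTORC1, at 1.03 [0.681 to 1.504] and 137.5, and Mt2, a metallothionein, at 0.306 [0.132 to 0.603] and 34.8. Nr3c1, the glucocorticoid receptor itself, was at 294 and 177, and Amd1, an enzyme of polyamine synthesis, at 238 and 53.7. In the unfolded protein and integrated stress response list 10 of 16 members were higher and 2 lower (median 1.01, percentile 99.9). Ppp1r15a was at 6.09 and 42.8 CPM and Ddit3 at 49.5 and 17.3.

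Fuel genes differed in direction between lists. In the list of fatty acid use and lipid handling 21 of 26 members were higher and 1 lower in KPCY (median 1.64, percentile 100). Pdk4, the kinase that shuts pyruvate dehydrogenase, was at 301 and 2077 CPM, and Acot2, a mitochondrial thioesterase, at 1.95 and 62.8. Its near-identical neighbour Acot1 had 0 control UMIs and was at least 72.5-fold higher, a value left uncertain because reads of such copies can be split in counting. Lipe (31.6 and 17.7) was lower. Of 24 glycolysis and glycogen genes, 14 were lower and 3 higher (median -1.10, percentile 0). Eno3, the muscle enolase, was at 609 and 22.8 CPM and Ldha at 238 and 12.5, while Ugp2, which makes UDP-glucose for glycogen, was at 557 and 2010. Of 28 genes of oxidative phosphorylation and mitochondrial biogenesis, 16 were lower and 2 higher (median -0.75, percentile 0.04). Cox7a1 (9.07 and 1.84) and Ppargc1b (199 and 45.8) were lowest, and Nrf1 (71.5 and 158) highest.

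Contractile genes were lower as a group. Of 30 fast sarcomere and contraction genes, 24 were at least 1.5-fold lower and 1 higher, with a median of -2.16 below all random lists. Myl1, a fast light chain, was at 6349 and 69.6 CPM, and Myoz1, a Z-disc protein, at 802 and 16.7. Myom1 (181 and 281) and Tcap (602 and 834) stood against the direction. Myh1, the type IIx myosin, was at 553 and 180, and Myh2, the type IIa myosin, at 188 and 50.6. The 15 slow and oxidative fibre genes had a median of 0.11 (mean -0.03, percentile 90.4), with 6 higher and 4 lower, and of -0.53 in type IIb-like clusters alone, so no direction holds. Tnnt1, the slow troponin T, was at 1.61 and 3.49, and Fhl2 at 1.61 and 0.448 (10 KPCY UMIs, log2 -1.84 [-3.004 to -0.83]). Of 23 genes of calcium handling and ion channels, 18 were lower and 2 higher (median -1.87, percentile 0), among them Casq1, the calcium buffer of fast fibres (905 and 24.9), and Sypl2, a triad membrane protein (248 and 1.93). Kcnj2 was higher, at 48.9 and 125. A Myh4 UMI was found in 30.1% [29.1 to 31.1] of KPCY myonuclei and 31.5% [27.7 to 35.4] of KPCY FAP-like nuclei, whose median depths of 2076 and 926 UMIs differ, and with every nucleus thinned to 500 UMIs in 10.4% and 19.3%. In control it was found in 93.9% and 37.7%, and thinned in 83.3% and 14.6%.

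Among regulators of growth, Igf1, a trophic factor of muscle, was at 268 CPM in control and 13.1 in KPCY myonuclei, and Igfbp5 at 169 and 1.52. Eif4ebp1, a brake on translation below mTOR, was at 4.75 and 108. In the IGF1, insulin and mTOR list as a whole 10 of 21 members were higher and 4 lower (median 0.42, percentile 78.2). The TGF-beta, activin and myostatin list had 12 of 23 members higher and 7 lower (median 0.67, percentile 99.5). Tgfbr3 was at 67.2 and 611 CPM, Tgfb2 at 69.9 and 20.6, and Mstn, myostatin, at 26.1 and 63.9. None of 12 BMP signalling genes was at least 1.5-fold higher and 6 were lower (median -0.58, percentile 27.2), with Id3 at 2.03 and 0.448 (log2 -2.18 [-3.32 to -1.19]).

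Cytokine-related genes went in both directions. In the STAT3, NF-kB and acute-phase list 10 of 20 members were higher and 5 lower (median 0.58, percentile 99.7). Il6ra, the interleukin-6 receptor, was at 1.95 [1.45 to 2.57] and 505 [495 to 514] CPM, 258-fold higher, and Lcn2 had 0 control UMIs and was at least 15.2-fold higher. Lifr (172 and 25.9) and Tnfaip3 (2.83 and 0.224, log2 -3.66 [-5.33 to -2.37]) were lower. Of 14 interferon response genes, 10 were lower and 2 higher (median -1.51, percentile 2.48). Gbp7 was at 17.7 and 0.358 (8 KPCY UMIs, log2 -5.63 [-6.85 to -4.64]) and H2-K1, whose counts can mix with those of related class I genes, at 9.19 and 23.2.

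Of 17 myogenic regulators, 9 were lower and 2 higher (median -0.81, percentile 1.42). Maf, a large Maf factor of fast fibre identity, was at 694 and 53.7 CPM and Myod1 at 16.9 and 0.627 (log2 -4.75 [-5.64 to -3.99]), while Mef2d was at 159 and 317. The denervation and neuromuscular junction list had 5 of 18 members higher and 8 lower (median -0.20, percentile 38.2), with Runx1 at 12.9 and 96.5 and Lrp4, the agrin receptor, at 35.1 and 2.06. In the dystrophin complex and costamere list 4 of 24 members were higher and 8 lower, with a median of -0.09 (percentile 9.87) that was 0.10 under TMM scaling. Flnc, filamin C, was at 127 and 577, Tln2 at 277 and 28.4, and Cav3 at 43.8 and 2.73. The basement membrane list had 3 of 18 members higher and 11 lower (median -0.81, percentile 12.7), with Sparc at 5.21 and 16.6 and Col4a3 at 13.4 and 1.57.

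Polyamine genes had 1 of 12 members higher and 7 lower (median -0.63, percentile 8.30). Smox, spermine oxidase, was at 159 and 5.82 CPM and Paox at 0.613 [0.350 to 0.995] and 5.24. The circadian clock list was mixed, with 8 of 18 members higher and 7 lower (median 0.45, mean -0.09, percentile 85.2). Cry2 was at 31.7 and 241, whereas Dbp, a clock output factor, was at 65.5 and 0.358 (log2 -7.51 [-8.73 to -6.53]). Immediate early and heat shock genes had 5 of 17 members higher and 8 lower, with a median of -0.11 (percentile 68.5) that was 0.08 under TMM scaling. Hsph1 was at 9.53 and 62.6 and Nr4a1 at 69.1 and 3.58.

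Across single genes the widest ratios upward belonged to Doc2b, a calcium sensor of exocytosis (0.345 [0.158 to 0.654] and 128 CPM, 370-fold), Il6ra, Tc2n (3 control UMIs, log2 7.64 [6.09 to 9.92]), Ddit4, Mt2, Fam65c (log2 6.58 [5.21 to 8.46]), Egln3, an oxygen-sensing prolyl hydroxylase (5.78 and 544), Kcnk5 (log2 6.52 [5.28 to 8.15]), Rassf4 (log2 6.48 [5.35 to 7.93]) and Acot1. Among the widest downward were those of Nrep (2 KPCY UMIs, log2 -8.49 [-11.54 to -6.63]), Plcd4 (544 and 1.66), Actc1, cardiac actin (86.9 and 0.269, log2 -8.34 [-9.78 to -7.21]), Mpp3 (3 KPCY UMIs, log2 -8.06 [-10.34 to -6.51]), Tmem233 (366 and 1.48), Iigp1 (1 KPCY UMI, log2 -7.83 [-13.14 to -5.34]), Myoz3 (log2 -7.73 [-8.86 to -6.80]), Ky, a protein of muscle maintenance (1109 and 5.24), and Sh3gl2 (375 and 1.97). By size alone, 1675 of 10815 genes with at least 100 UMIs were at least 2-fold higher and 2683 at least 2-fold lower, and 2130 and 2313 under TMM scaling. Myonuclei of the libraries fell into different clusters (1, 2, 6, 11 and 15 for control, 0, 3, 4, 8 and 16 for KPCY, 18 for both), and TMM scaling moved the median of all genes from -0.09 to 0.09, so ratios near 1 have no firm sign.

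**Figure D2:**
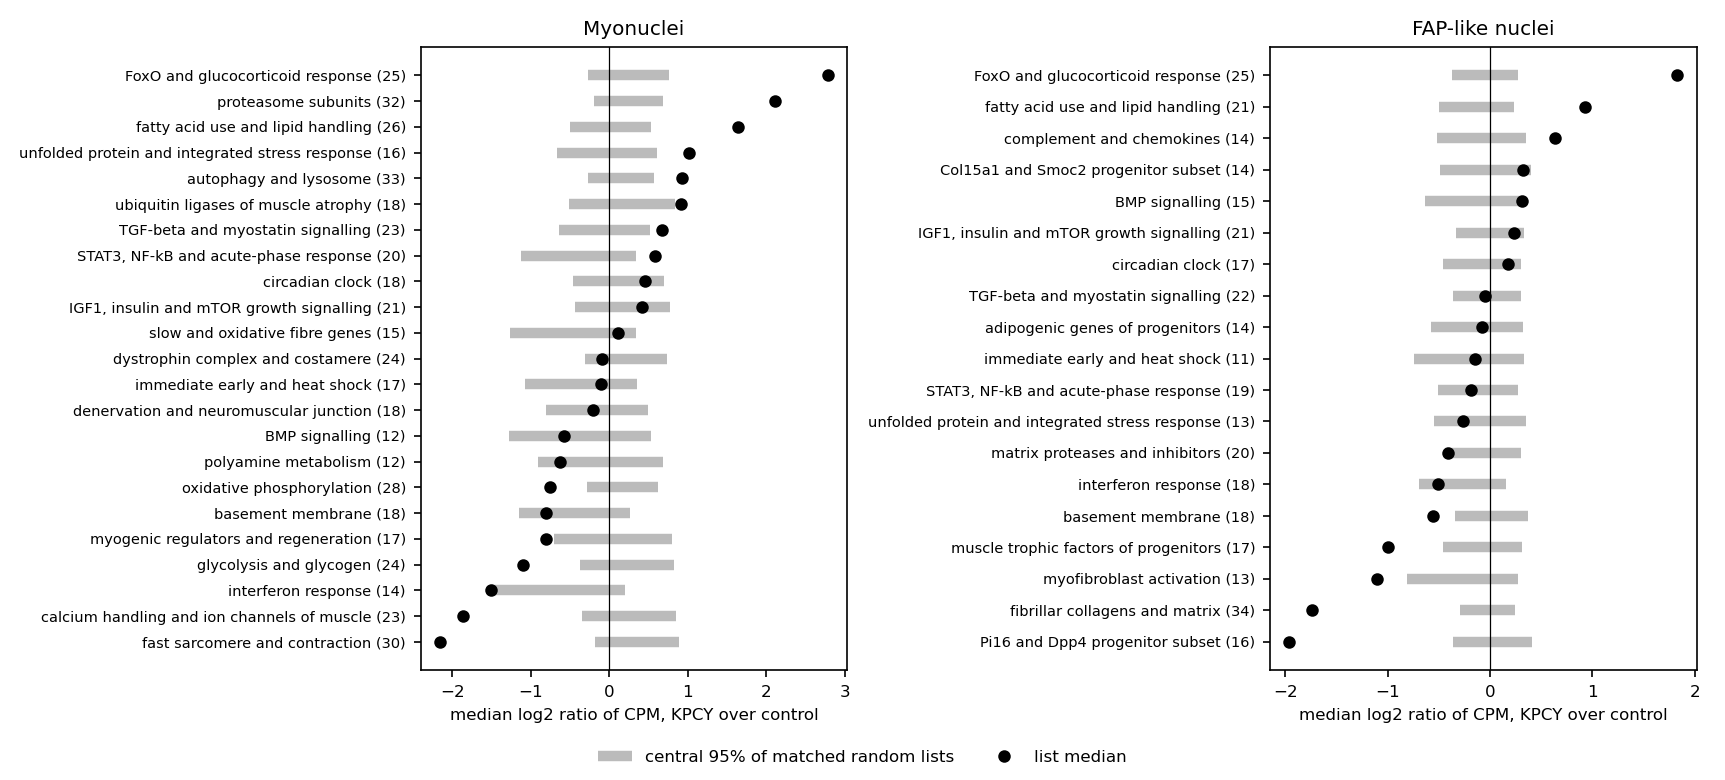
Median log2 ratio of CPM, KPCY over control, of each gene list in myonuclei and FAP-like nuclei (black points, measured members in parentheses), with the central 95% of matched random lists as grey bars. In myonuclei FoxO and glucocorticoid genes lie at 2.79 and fast sarcomere genes at -2.16, and in FAP-like nuclei the Pi16 and Dpp4 subset lies at -1.96 and collagens at -1.74.

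The third comparison asked how FAP-like nuclei differed. Those of the KPCY library held far fewer transcripts of matrix genes and of the Pi16 and Dpp4 progenitor state, and more of glucocorticoid-responsive and some complement genes. Col1a1, a chain of the main fibrillar collagen, was at 285 [267 to 304] CPM in control and 23.4 [13.4 to 38.0] in KPCY, 12.2-fold lower. Col3a1 was at 1572 [1529.5 to 1614] and 164 [135 to 197], 9.58-fold lower. The progenitor marker Pi16 was at 290 [272 to 308] and 24.9 [14.5 to 39.9]. Igfbp3, which binds and carries IGF1, was at 7.98 [5.26 to 11.6] and 520 [467 to 577], 65.2-fold higher. Of the markers used to name FAP-like clusters, Pdgfra (762 and 477) and Dcn, decorin (2021 and 3557), stood closer. Col1a1, Col3a1 and Pi16 belong to the same marker set, as do Lum, Col1a2 and Smoc2, all lower in KPCY.

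Of 34 fibrillar collagen and matrix genes, 25 were at least 1.5-fold lower and 3 higher in KPCY FAP-like nuclei, with a median log2 ratio of -1.74 below all random lists. Col6a2 was at 245 and 24.9 CPM (log2 -3.30 [-4.08 to -2.61]). Against that direction stood Lox, the enzyme that crosslinks collagen, at 11.8 and 161, and Fbln1 at 35.2 and 86.4. The basement membrane list had 8 of 18 members lower and 1 higher (median -0.56, percentile 0.14). Col15a1 was at 400 and 14.6 CPM (log2 -4.77 [-5.84 to -3.89]) and Col18a1 at 64.1 and 5.86 (log2 -3.45 [-5.34 to -2.08]), while Col4a4 was at 278 and 401. Matrix proteases and inhibitors had 9 of 20 members lower and 4 higher (median -0.41, percentile 3.29). Adamtsl3 was at 586 and 110, whereas Mmp11, stromelysin-3, was at 12.1 and 198 and the membrane protease Mmp14 at 57.9 and 186. The myofibroblast list had 8 of 13 members lower and 3 higher, with a median of -1.11 (percentile 0.305). In it, Thy1 had 2 KPCY UMIs (log2 -3.76 [-6.82 to -1.88]), while Ctgf (14.5 and 52.7) and Runx1 (36.3 and 108) were higher.

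The progenitor subsets lay apart. Of 16 genes of the Pi16 and Dpp4 subset, the stem-like adventitial state, 13 were lower and 1 higher (median -1.96, percentile 0). Dact2 was at 69.1 and 7.32 CPM (log2 -3.24 [-4.88 to -1.996]) and Sema3e at 29.0 and 76.1. The Col15a1 and Smoc2 subset had 4 of 14 members higher and 5 lower (median 0.32, mean -0.06, percentile 94.5), with Apod, a lipocalin, at 111 and 1473, Thbs1 at 8.86 and 104, and Lum at 114 and 14.6 (log2 -2.96 [-4.03 to -2.06]). Of 17 trophic factors of progenitors 12 were lower and 1 higher (median -1.001, percentile 0.01). Igf1 was at 265 and 57.1 CPM and Gas6 at 57.9 and 184. Adipogenic genes were balanced, 5 higher and 5 lower of 14, with a median of -0.07 (percentile 56.4) that was 0.00 under TMM scaling. Cd36 was at 16.3 and 119, with 0 KPCY UMIs left after subtraction of free RNA, and Zfp423, a determinant of preadipocytes, at 139 and 24.9 (log2 -2.48 [-3.27 to -1.79]).

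Of 25 FoxO and glucocorticoid response genes, 21 were higher and 1 lower in KPCY FAP-like nuclei (median 1.83, percentile 100, and 1.20 after subtraction of free RNA). Fkbp5 was at 412 and 1252 CPM and Klf15 at 5.91 [3.61 to 9.13] and 51.3 (log2 3.12, then 2.03 after subtraction), while Nr3c1 was at 438 and 247. The fatty acid and lipid list had 14 of 21 members higher and 1 lower (median 0.93, percentile 100, but 0.14 after subtraction of free RNA), led by Plin4 (7.09 [4.54 to 10.6] and 164). Complement and chemokine genes had 7 of 14 members higher and 4 lower (median 0.64, percentile 99.9). C4b, whose counts can mix with those of a near-identical copy, was at 7.98 [5.26 to 11.6] and 113, and Cxcl13, a B cell chemokine, at 2.66 [1.22 to 5.05] and 52.7. C3 (132 and 63.0) and Cd55 (306 and 60.04) were lower. Muscle fibre RNA was more abundant in these nuclei in KPCY: core myofibre genes stood at 2.88% of their level in the whole control library and 9.94% of that in the whole KPCY library. The level of contractile genes gave higher estimates, 6.62% and 33.4% of UMIs, in which free RNA and doublets are not separated. The measures disagree most in KPCY, where 7 of 30 fast sarcomere genes were higher in FAP-like nuclei than in myonuclei. Subtraction of free RNA used the higher estimates, so it may remove too much.

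Among the remaining lists of FAP-like nuclei, STAT3, NF-kB and acute-phase genes had 6 of 19 members higher and 6 lower (median -0.19, mean 0.19, percentile 31.4, and 0.38 over members with at least 100 UMIs), with Il6ra at 107 and 492 CPM and Relb at 38.1 and 5.86 (log2 -2.70 [-4.60 to -1.31]). Subtraction of free RNA left 358 of 363 control and 225 of 336 KPCY UMIs of Il6ra. Of 18 interferon genes 9 were lower and 1 higher (median -0.51, percentile 11.4), with Xaf1 at 2 KPCY UMIs (log2 -3.28 [-6.34 to -1.38]) and Ifit2 at 24.8 and 64.4. The TGF-beta list had 6 of 22 members each way, with a median of -0.05 (percentile 41.1) that was 0.03 under TMM scaling, and Fstl1 at 673 and 217. BMP genes had 3 of 15 members higher and 6 lower, with a median of 0.32 (percentile 97.8), a mean of -0.15 and a thinned median of -0.10, so no direction holds. Bmp4 was at 79.8 and 217 and Bmp6 at 113 and 33.7 (log2 -1.74 [-2.42 to -1.14]). The IGF1 list had 8 of 21 members higher and 5 lower (median 0.23, percentile 90.8), with Igfbp5 at 230 and 26.4 (log2 -3.13 [-3.89 to -2.46]). The stress response list had 2 of 13 members higher and 5 lower (median -0.26, percentile 19.95), with Atf5 at 104 and 32.2 (log2 -1.69 [-2.38 to -1.07]) and Ddit4 at 9.46 and 60.04. Subtraction of free RNA left 31.3 of 32 control and 10.7 of 41 KPCY UMIs of Ddit4. The clock list had 6 of 17 members each way, with a median of 0.18 (percentile 90.3) that was -0.34 after subtraction of free RNA, and Dbp, with 0 KPCY UMIs, was at least 5.45-fold lower. Immediate early and heat shock genes had 3 of 11 members higher and 2 lower (median -0.15, mean 0.12, percentile 53.2), with Fosl2 at 28.4 and 117 and Jun at 81.6 and 23.4 (log2 -1.80 [-2.63 to -1.07]).

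The widest ratios upward in FAP-like nuclei mixed muscle fibre genes with genes that myonuclei barely held. Trim63 (11.52 and 1161 CPM), Fbxo32 (21.0 and 633), Myo18b (6.21 [3.84 to 9.49] and 151), Plin4, Nrap (16.5 and 354), Fam134b (17.7 and 357) and Pdk4 (16.8 and 309) were at higher levels in KPCY myonuclei, and subtraction of free RNA left all 7 with 0 KPCY UMIs and turned the ratio of Foxo1 round (255 and 592, then log2 -0.42). That subtraction took 33.4% of KPCY UMIs, above the 9.94% level of core myofibre genes, so the zeros and the turn of Foxo1 may rest on its size. Igfbp3 (3.72 CPM in KPCY myonuclei), Sox4, a transcription factor (12.4 and 331, myonuclei 9.99), and Galnt15, a glycosyltransferase (68.9 and 1335, myonuclei 7.08), were at far lower levels in myonuclei. Among the widest downward were those of Cd248, endosialin (1 KPCY UMI, log2 -5.07 [-10.38 to -2.57]), the hyaluronan synthase Has2 (3 UMIs, -4.86 [-7.14 to -3.30]), Oaf (3 UMIs, -4.80 [-7.09 to -3.25]), Col15a1, Rcn3 (1 UMI, -4.68 [-9.99 to -2.18]), Smtn (1 UMI, -4.67 [-9.98 to -2.16]), Adamts16 (0 UMIs, at least 24.4-fold lower), Arhgap20os (1 UMI, -4.57 [-9.89 to -2.07]) and the collagen chaperone Serpinh1 (3 UMIs, -4.50 [-6.78 to -2.94]). Arhgap20os is an antisense gene, and its counts stay uncertain because the strand setting of the counting is not given in the sources used here. By size alone, 404 of 6421 genes with at least 100 UMIs were at least 2-fold higher and 876 at least 2-fold lower, 475 and 780 under TMM scaling, and 443 and 1368 after subtraction of free RNA.

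**Figure D3:**
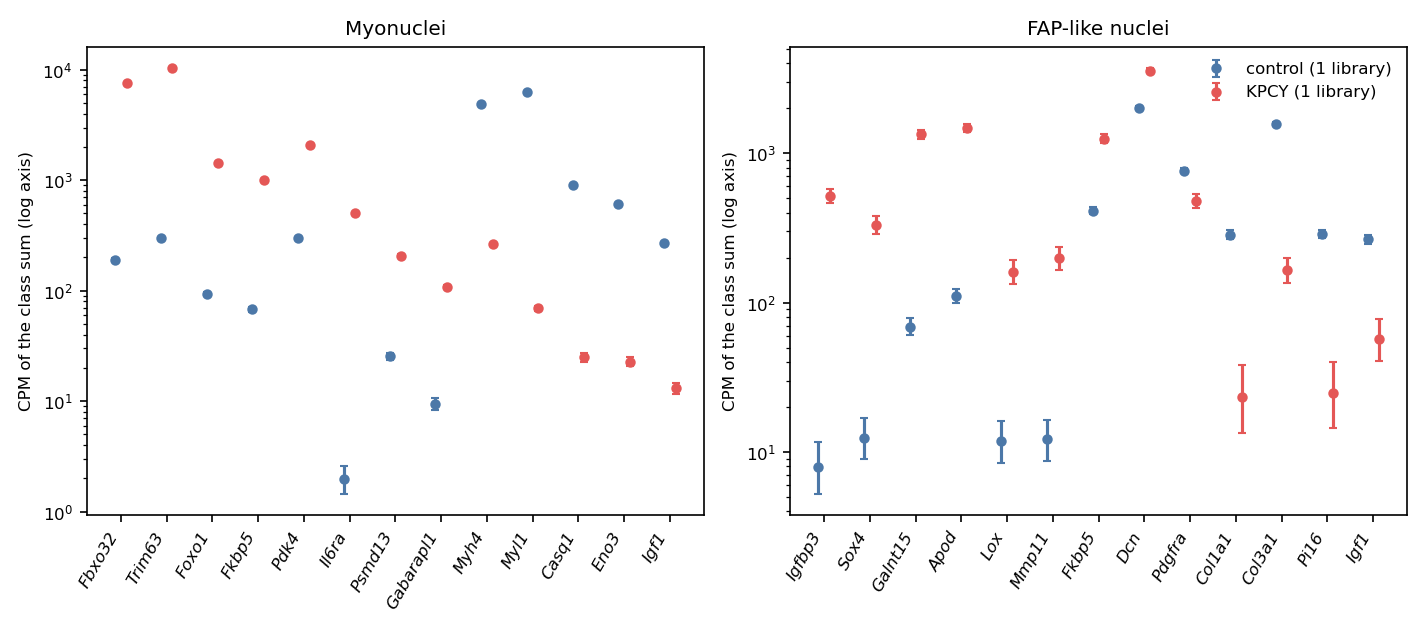
CPM of selected genes (log axis) in the summed myonuclei and FAP-like nuclei of each library, 1 point per library with exact Poisson 95% intervals. In myonuclei Fbxo32 lies at 191 and 7540 and Myh4 at 4940 and 263, and in FAP-like nuclei Igfbp3 lies at 7.98 and 520 and Col1a1 at 285 and 23.4.

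The fourth comparison covered endothelial-like nuclei (cluster 10, shared by both libraries). Fkbp5 was higher in the KPCY library, and interferon response and endothelial activation genes were lower in the whole class but within the central 95% of random lists in nuclei with little muscle fibre RNA. Of 15 interferon genes, 14 were at least 1.5-fold lower and none higher (median -1.40, percentile 0), and in nuclei with under 1% of UMIs from core myofibre genes, a limit chosen after the data were seen, 6 of 15 were lower and none higher (median -0.32, percentile 5.24). Bst2 was at 79.0 and 13.2 CPM (log2 -2.58 [-3.75 to -1.54]). Fkbp5 was at 68.1 and 1261 in all endothelial-like nuclei and at 68.2 and 1451 in those with little muscle fibre RNA. Dlg2 (356 and 18.5, log2 -4.26 [-5.17 to -3.47]), Tcf15, a transcription factor of lipid-transporting capillaries (274 and 22.5, log2 -3.61 [-4.43 to -2.87]), and Sybu (277 and 26.5, log2 -3.39 [-4.15 to -2.70]) were among the lowest, beside the muscle genes Myl1 and Mylpf. The highest, Trim63 (13.2 [4.83 to 28.7] and 5274), Pdk4 (3 control UMIs, log2 7.24 [5.68 to 9.52]), Fbxo32 (28.5 [15.2 to 48.8] and 3888), Trp63 (2 control UMIs, log2 6.93 [5.07 to 9.98]) and Nrap (17.6 [7.58 to 34.6] and 1958), were abundant in myonuclei, and subtraction of free RNA left all but Nrap with 0 KPCY UMIs.

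Most of the other endothelial lists moved when nuclei with much muscle fibre RNA (free RNA or doublets), an estimated 9.71% of UMIs in control and 59.3% in KPCY, were left out, so the values with under 1% core myofibre UMIs follow each main value. STAT3, NF-kB and acute-phase genes had 1 of 13 members higher and 3 lower (median 0.10, percentile 80.1), then 7 of 11 higher and 1 lower (median 0.77, percentile 99.99). Activation and angiogenesis genes had 12 of 21 members lower and 2 higher (median -0.71, percentile 0.43), then a median of -0.06 (percentile 30.5). Vwf, a clotting factor of endothelium, was at 360 and 348, then 361 and 774, and Cxcl12 at 364 and 86.0, then 365 and 156. Barrier and lipid transport genes had a median of -0.44 (percentile 13.1), then 0.32 (percentile 96.4), and Lpl, lipoprotein lipase, was at 169 and 397, then 169 and 543, a direction that turned round with each library clustered on its own (log2 -0.76). Medians of the other lists were -0.72 (percentile 3.02), then -0.23 (percentile 6.43), for basement membrane (0.17 after subtraction of free RNA), 0.71 (percentile 99.6), then 0.17 (percentile 83.7), for the clock, and -0.93 (percentile 1.245), then -0.87 (percentile 6.24), for immediate early and heat shock genes, among which Egr1 had 1 KPCY UMI (log2 -5.98 [-11.32 to -3.41]).

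The fifth comparison covered macrophage-like nuclei (cluster 13, 231 control and 59 KPCY nuclei). Resident macrophage genes were lower and Fn1, fibronectin, was higher in the KPCY library. Of 16 resident macrophage genes 14 were at least 1.5-fold lower and none higher (median -1.25, percentile 0), and in nuclei with under 1% core myofibre UMIs 12 of 16 were lower and 1 higher (median -0.90, percentile 0.01). Mrc1, the mannose receptor CD206, was at 2833 [2660 to 3015] and 1062 [864 to 1291] CPM, Cbr2 had 3 KPCY UMIs (log2 -2.71 [-5.02 to -1.11]) and Folr2 had 1 (log2 -3.60 [-8.93 to -1.04]). Fn1 was at 285 and 1168. The inflammation list had 3 measured members, with a median of 0.52 (percentile 84.8), then 1.24 (percentile 99.5). Complement genes had 4 of 5 members lower (median -1.59, percentile 0.1), then -1.23 (percentile 0.235), with C1qa at 268 and 106 (log2 -1.34 [-2.44 to -0.40]). By contractile genes an estimated 6.33% of control and 51.8% of KPCY UMIs in this class were muscle fibre RNA. Such RNA lowers the CPM of genes that fibres lack. Part of the lower values of Mrc1, C1qa, Cbr2, Folr2 and other macrophage genes may therefore be dilution.

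Interferon genes in macrophage-like nuclei had 7 of 9 members lower and none higher (median -1.16, percentile 0.31), then a median of -0.59 (percentile 4.96), with Oas2 at 1 KPCY UMI (log2 -3.15 [-8.50 to -0.57]). Fkbp5 was at 123 and 1645. The lowest single genes were Cmah (685 and 74.3, log2 -3.20 [-4.53 to -2.14]), Reps2 (log2 -3.17 [-4.63 to -2.02]), Atp5o (log2 -3.10 [-4.74 to -1.84]), Ddx60 (log2 -3.01 [-4.34 to -1.94]) and Tanc2 (1390 and 191, log2 -2.86 [-3.63 to -2.19]), and the highest, Trim63, Nrap, Fbxo32, Rbfox1 and Tacc2, were all abundant in KPCY myonuclei. Muscle fibre RNA made up an estimated 6.33% of macrophage-like UMIs in control and 51.8% in KPCY, and its spread over classes was uneven, so doublets are not excluded as part of it.

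In mural-like nuclei (149 control and 103 KPCY), with muscle fibre RNA (free RNA, mixed nuclei or doublets) at an estimated 42.3% and 51.8% of UMIs, the widest ratios followed those of myonuclei. Trim63 (68.4 and 3810 CPM), Fam134b (30.9 [16.9 to 51.9] and 1147) and Fbxo32 (128 and 2973) were highest, and Myl1 (1987 and 22.6 [6.16 to 57.9]), Ky (1 KPCY UMI, log2 -6.04 [-11.35 to -3.54]) and Myoz1 (1 KPCY UMI, log2 -5.55 [-10.87 to -3.04]) lowest. Subtraction of free RNA left fewer than 1 KPCY UMI of each of these 6 genes. Fkbp5 was at 102 and 667. Over all kept nuclei, 3 of 13 mitochondrially encoded transcripts were at least 1.5-fold higher and none lower (median 0.37, percentile 75.2), and all 5 haemoglobin and erythroid transcripts were lower (median -1.27, percentile 3.77), an order that turned round with the mean of single nuclei (0.89) and with nuclei thinned to 500 UMIs (0.82). None of the 7 tumour epithelium transcripts reached 30 UMIs.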

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

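Chosen only after the results were seen were the tests of unnamed clusters and dilution for the share of FAP-like nuclei, those of free RNA and depth for the matrix genes, and those of depth for the myonuclear lists.

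Several values had opposite signs in different classes of nuclei, and none of these differences was tested. The complement and chemokine list had a median log2 ratio of 0.64 in FAP-like and -1.59 in macrophage-like nuclei, a difference of 2.23. Dcn was at 0.82 in FAP-like and -0.77 in endothelial-like nuclei, a difference of 1.58, but the endothelial-like value was 3.08 with no mitochondrial limit and 0.0630 with each library clustered on its own, so the opposite signs do not hold. Myh1 was at 1.19 in FAP-like nuclei and -1.62 in myonuclei, a difference of 2.81, but subtraction of free RNA left 0 FAP-like UMIs in both libraries, so no FAP-like value of its own is left. Myh4 was at 1.61 in FAP-like nuclei, -4.23 in myonuclei and -1.10 in endothelial-like nuclei, differences of 5.84 and 2.70. The endothelial-like value of Myh4 was 0.19 after subtraction of free RNA, which ends the opposite sign there. In FAP-like nuclei subtraction left 74.5 of 988 control and 538 of 607 KPCY Myh4 UMIs. The whole-library profile it used holds little Myh4 in KPCY (263 CPM in myonuclei, 889 in FAP-like nuclei). Subtraction therefore cannot decide whether free RNA accounts for the rise there. Whether FAP-like nuclei hold Myh4 of their own stays open.

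FAP-like nuclei had a smaller share in the KPCY library. With every unnamed KPCY nucleus counted as FAP-like the share would be 13.1%, below the lower control limit of 15.9%, but with each library clustered on its own it would be 16.0% against a limit of 15.2%. Among named nuclei outside myonuclei the share was 49.6% against 65.9% in control, but 70.5% against 64.7% with each library clustered on its own and 80.9% against 81.4% when clustered without genes 2-fold apart. The named total depended on the endothelial-like class. Its log2 share ratio was -1.83 with each library clustered on its own, and it had 0 nuclei without those genes. Over all kept nuclei the FAP-like share stayed lower in KPCY under these clusterings, at 6.17% against 15.9% and 5.53% against 16.1%. Among all nuclei outside the myonuclear clusters of the main clustering it was 29.3% against 49.1%. The named shares thus cannot decide on dilution by myonuclei, and misplaced clusters are not excluded. Control nuclei thinned to the KPCY depth of each class and counted again from 500 UMIs still gave 15.6%, against an upper KPCY limit of 5.89%. The depth of nuclei that never reached the file minimum is unknown, so misplaced clusters, dilution, a loss of shallow nuclei and unequal release from the tissue cannot be told apart from a smaller population, and the tumour and the library are confounded.

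Matrix genes were lower in FAP-like nuclei of the KPCY library, with a collagen and matrix median of -1.74. The median was -1.39 after subtraction of free RNA, so free RNA as estimated here does not account for the whole difference. With every nucleus thinned to 500 UMIs it was -1.45. Random thinning keeps the expected share of each gene in a nucleus, so that value cannot decide on depth. Against the sub-clusters of the control FAP-like nuclei taken singly the median ran from -1.86 to -1.36, which argues against the loss of 1 matrix-rich subset as the whole cause. A lower output of matrix transcripts per nucleus in the tumour-bearing mouse is a hypothesis these values may favour, found and tested on the same libraries. A difference between mice or preparations stays open.

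Atrophy ligases were higher and fast sarcomere genes lower in KPCY myonuclei, with medians of 0.91 and -2.16. Thinned to 500 UMIs the medians were 0.86 and -1.97. Random thinning keeps the expected share of each gene in a nucleus, so these values cannot decide on depth. Over 25 pairs of a KPCY and a control myonuclear cluster the sarcomere median ran from -2.92 to -1.10, so no pairing of subtypes removes it. The atrophy median ran from 0.46 to 0.98 with 20 of 25 pairs past 1.5-fold. The pairs short of it joined clusters unlike in markers, such as KPCY cluster 16 (Col22a1) and control cluster 11 (Myh2 and Myh1) at 0.46. Pairs that shared such markers stayed past it, at 0.64 for clusters 16 and 15 and 0.83 for clusters 3 and 11. Type IIb-like clusters alone gave 0.82. The low pairs thus do not show that a different mix of subtypes accounts for the ligase difference, and a part is not excluded. A response of fibres to the tumour and a difference between mice or preparations both stay open.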

How the results depend on the processing

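Added after the data were seen were removal of the 8% highest doublet scores, shares without unnamed clusters, the median of all genes set to 0, nuclei with under 1% core myofibre UMIs, and clustering without genes 2-fold apart. No paired analysis was possible because the labels share nothing between the libraries but the replicate number 1. Across the principal results 88 values stayed near the reported one, 13 moved and 0 changed sign. Many of these values are counts of genes, which cannot change sign. Such counts were called near over a wide range, 1117 to 2512 for the 1675 higher myonuclear genes. Settings in which FAP-like nuclei had no value are not in this tally. Across the others 32 values changed sign from a gene ratio of at least 1.5-fold, a list median outside the central 95% of random lists or a share whose counting interval left out 0. Another 91 changed sign from smaller values, 52 of them genes, 35 list medians and 4 the endothelial-like share. The log2 ratio of the myonuclear share lay between 0.28 and 0.33, the atrophy ligase median between 0.82 and 1.09 and the collagen median between -1.87 and -1.39. By a rule added after the values were seen, no ratio is given where both libraries hold 3 counts or fewer after a change of setting or where the floor alone sets the sign, and list medians leave such members out. FAP-like nuclei had no value with no mitochondrial limit, at resolution 0.4 or with the 8% highest doublet scores removed, since the KPCY ones fell in an unnamed cluster. Endothelial-like nuclei had none when clustered without genes 2-fold apart, small classes had none under 20 nuclei, and free RNA and core myofibre settings do not apply to myonuclei. Depth limits the classes outside myonuclei, where many KPCY genes rest on fewer than 30 UMIs. TMM scaling moved the median of all genes from -0.10 to -0.02 in FAP-like, from -0.08 to 0.22 in endothelial-like and from -0.33 to 0.03 in all nuclei. The cause was not tested for any value below, except that counts of genes move with the UMI limit by construction and that subtraction removes genes at free RNA level.

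The log2 ratio of the FAP-like share (-1.61) was -1.94 from 500 genes, -1.36 with each library clustered on its own, -2.46 from 1000 UMIs and -0.75 outside the myonuclear clusters. The atrophy median was 1.09 under TMM, and the collagen median -1.45 thinned and -1.39 with free RNA subtracted. From 300 UMIs 1749 myonuclear genes were 2-fold lower. In FAP-like nuclei 673 genes from 30 UMIs and 192 from 300 were 2-fold higher, and 1909 from 30, 319 from 300 and 1368 with free RNA subtracted 2-fold lower.

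The 32 values, as log2 ratios, follow by setting. At resolution 0.4, mural-like: the share 0.0807, Myh1 0.0425. At resolution 1.6: mural-like Myh1 0.73. Clustered without genes 2-fold apart: mural-like Dcn 1.73. Each library on its own: FAP-like Pax7 1.27, endothelial-like Dcn 0.0630, Lpl -0.76 and Icam1 0.98, macrophage-like Dcn 1.12. With no mitochondrial limit: endothelial-like Dcn 3.08. Mean of single nuclei: FAP-like Pparg 0.0771. Thinned to 500 UMIs: the FAP-like BMP median -0.10, myonuclear Bmp5 0.57, endothelial-like Ifih1 0.15.

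With free RNA subtracted: the endothelial-like clock median -0.0170 and activation median 0.34, FAP-like Foxo1 -0.42, endothelial-like Ifih1 0.0412, Foxo1 -0.69 and Myh4 0.19. Bounds, since subtraction left 0 UMIs in KPCY: FAP-like Fam134b -1.65 and Fbxo32 -1.33, endothelial-like Il6ra -2.44, Fbxo32 -1.84 and Vegfa -2.30, macrophage-like Foxo1 -2.20, mural-like Pdk4 -2.43 and Fbxo32 -2.60. A bound with 0 UMIs left in control: mural-like Myh4 5.74. With under 1% core myofibre UMIs: endothelial-like Vegfa -0.12, macrophage-like Foxo1 -0.90, mural-like Myh4 0.0412.

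List medians that changed sign from values within the central 95% reached -0.53 for slow fibre genes (type IIb-like clusters), 0.19 for myonuclear and 0.19 for FAP-like immediate early genes, 0.10 for the dystrophin list, 0.38 for STAT3, 0.23 for TGF-beta, -0.34 for the clock and 0.25 for adipogenic genes in FAP-like nuclei, 0.17 for basement membrane and 0.62 for barrier genes in endothelial-like nuclei, and 0.89 for haemoglobin. The endothelial-like share lay between -1.83 and 0.96.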

Other observations

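The genes in the first paragraph and the test of Myh4 were chosen only after the values had been seen.

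A few other genes that the named-genes rule had not taken also stood higher in FAP-like nuclei of the KPCY library, picked singly and not as a theme, as CPM in control, in KPCY and, last, in KPCY myonuclei. Zbtb16, a transcription factor, was at 447, 3322 and 2066, the complement gene C7 at 234, 829 and 1.75, Inmt, a methyltransferase, at 39.0, 605 and 3.85, and Cyp1b1 at 8.57 [5.74 to 12.3], 120 and 0.269. Nampt, an enzyme of NAD synthesis, was at 28.7, 400 and 183 and Trp53inp1 at 33.1, 507 and 223. All these genes stood lower in KPCY myonuclei than in KPCY FAP-like nuclei. Fibre RNA at myonuclear levels would therefore lower rather than raise their FAP-like CPM. Such RNA made up an estimated 33.4% of KPCY FAP-like UMIs by contractile genes and less by core myofibre genes. Lower were Smoc2 (1254 and 561) and Col1a2 (730 and 215).

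Myh4 UMIs in KPCY myonuclei may be free RNA left from the tissue, a hypothesis tested by comparison with FAP-like nuclei of the same library. A Myh4 UMI was present in 30.1% of KPCY myonuclei, not above the upper limit of 35.4% in FAP-like nuclei. Thinned to 500 UMIs, 10.4% of KPCY myonuclei and 19.3% of KPCY FAP-like nuclei held one, against 83.3% and 14.6% in control. Thinned KPCY endothelial-like nuclei held one in 9.70% [6.85 to 13.2], macrophage-like in 8.47% [2.81 to 18.7] and mural-like in 13.6% [7.64 to 21.8]. Subtraction of free RNA left 538 of 607 Myh4 UMIs in KPCY FAP-like nuclei. It used the whole-library profile, mostly of myonuclei, in which Myh4 was at 263 CPM against 889 in FAP-like nuclei. Most of these UMIs could thus not be removed whatever their source. Whether FAP-like nuclei are a good measure of free Myh4 RNA stays open. Of 30 fast sarcomere genes 7 were higher in FAP-like nuclei than in myonuclei of the KPCY library, and 0 in control. How much Myh4 transcription remained in KPCY myonuclei stays open.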
